A study of Homo sapiens with 10 samples.

How the data were processed

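ATAC-seq was done on aortic smooth muscle cells of 5 donors in 2 states, proliferative (with serum) and quiescent (without serum for 24 hours), 10 samples in all. Per the submitters' processing notes, reads were aligned with Bowtie2, handled with SAMtools and peaks were called with MACS2 on hg38 (GRCh38). Versions, read filters and the treatment of reads for the position of the transposase are not given in the sources used here. The files used are 2 peak lists, 1 for each state, each merged over 5 donors by the authors; whether reads were merged before peaks were called is not given in the sources used here. The lists give each peak's position, summit, fold enrichment over background and significance. The fold enrichment, a ratio, is the authors' deposited value for the summit of each peak and is not normalised between the lists. The −log10 p and −log10 q are the authors' deposited values from the test of the caller within each list. The lowest −log10 q was 1.00 in both lists, so peaks below about that level were not listed. Both scores were used only to describe, rank or filter peaks within their own list.

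The proliferative list held 171120 peaks and the quiescent list 166652. Peaks on chromosomes 1 to 22 and X were kept, and 546 and 508 peaks elsewhere were left out. No peak overlapped another of its own list, so each peak is 1 region. The regions covered 78.6 Mb and 77.1 Mb, with median widths of 364 bp and 369 bp and shortest widths of 154 bp and 145 bp. Read totals were not used here. Background was taken from the steps between the 10 commonest fold values, since the fold of the caller is the summit pileup plus 1 over the background plus 1. All 10 pileups came out whole within 0.01 in each list, and the p-values recomputed from them differed by at most 0.000217 in −log10 p. Because the lists may differ in depth and enrichment, a region can be restricted to a list because of the threshold alone.

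A region was called shared when it overlapped a region of the other list by at least 1 bp, and otherwise restricted. Gene positions came from a RefSeq table of assembly GRCh38.p14 with 19970 protein-coding genes on these chromosomes. That table has no strand, so promoters, which had been planned, were replaced by gene ends: a region's summit within 1 kb of either end of a protein-coding gene for the shares, and any overlap with the 1 kb around either end for counts of genes. The overlap was chosen for the counts of genes after the summit had been tried. Each region was assigned to the shortest gene span holding its summit, or else to the nearest span within 50 kb; this replaced the planned nearest transcription start. Motif shares had been planned and were not run, since no genome sequence was used here.

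There were 19 gene lists with 353 genes, fixed before the data were examined: contractile, cell cycle, quiescence and growth arrest, immediate early serum response, growth factor, TGF-beta and BMP, extracellular matrix, inflammation and protease, sterol and lipid, glucocorticoid response, artery disease loci, vascular regulators, HOX, housekeeping, and markers of endothelial cells, macrophages, T cells, fibroblasts and hepatocytes. All genes matched the table, 1 of them by a synonym. For each list, the share of proliferative-restricted among its restricted regions was set against 10000 random lists of the same size, drawn from about 200 genes closest to each member in number of regions. The percentile describes these 2 lists and is not a p-value for the states. Genes named in the text followed a rule fixed before the data were examined: the 10 strongest restricted regions of each list; the 8 genes with the largest excess each way; in each gene list up to 2 genes each way with an excess of at least 3 regions and up to 3 genes with a region at an end in 1 list only; and MYH11, ACTA2, TAGLN, CCND1, MKI67, FOS, TCF21 and PDGFD. Some genes that this rule takes are not reported here. Other genes named in the closing observations were chosen after their values were seen.

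The overlap and assignment steps were tested on simulated data and against direct searches. Of 20000 simulated regions, 70.1% were placed to overlap and 70.1% were recovered, and 0 of 1500 overlap calls and 0 of 1000 gene assignments differed from a direct search. With list labels drawn at random for the 19 gene lists, 6.05% of 380 balances fell outside the central 95%. A planted proliferative share of 70% at the 19 contractile genes, with their 158 restricted regions, was found above that range in 20 of 20 simulations. Alternatives fixed beforehand were a −log10 q of at least 2, the 50000 strongest regions of each list, a reciprocal overlap of 50%, summits within 100 bp, a −log10 q of at least 5 in the list itself, windows of 500 bp and 2 kb at gene ends, and assignment within 10 kb and 100 kb. Others were added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.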

Results

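Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in smooth muscle cells cultured from human aorta. Cells of 5 donors were kept either with 5% fetal bovine serum (proliferative, n = 5 samples) or without serum for 24 hours (quiescent, n = 5 samples). Smooth muscle cells form the contractile layer of the artery wall, and the series addresses genes for coronary artery disease in these cells. The files analysed here are 1 list of peaks per state, each pooled over the 5 donors by the authors. There was therefore no spread between replicates, no difference below was tested across donors, and the intervals given are 95% Wilson intervals that cover counting error only. The proliferative list held 170574 regions on chromosomes 1 to 22 and X and the quiescent list 166144. Read totals were not used here. The background pileup behind the lists was 6.55 for the proliferative and 5.99 for the quiescent list, a ratio of 1.09, or 1.03 per bp of the shortest region of each list.

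Most accessible regions were listed in both states, and the ends of genes central to smooth muscle and to growth were among them. ACTA2, encoding smooth muscle actin, TAGLN, encoding transgelin, the growth-induced transcription factor FOS, the cyclin gene CCND1, the proliferation marker MKI67 and the coronary disease genes TCF21 and PDGFD each had a region of both lists at an end of the gene. Of the proliferative regions, 117453 overlapped a quiescent region (68.9%, interval 68.6 to 69.1). Of the quiescent regions, 117164 overlapped a proliferative region (70.5%, interval 70.3 to 70.7). The remaining 53121 proliferative and 48980 quiescent regions are called restricted here, which means that they had no overlap in the other list at its own threshold and not that they were closed there. MYH11, encoding smooth muscle myosin, had 0 regions in either list; it lies in a stretch of chromosome 16 from 14419559 to 17038647 (hg38) that held no region of either list.

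Gene ends with a region were largely the same in both states. Of 19970 protein-coding genes, 13797 (69.1%) had a region of both lists within 1 kb of an end, 694 had one in the proliferative list only, 720 in the quiescent list only, and 4759 in neither. Long gene-rich stretches without a region of either list, treated in the closing observations, held 625 genes. An end in neither list was thus not necessarily closed. Restricted regions were less often at gene ends than shared ones. In the proliferative list, 11.9% of shared regions (interval 11.67 to 12.04) and 3.21% of restricted regions (interval 3.07 to 3.37) lay within 1 kb of an end. In the quiescent list the shares were 11.7% (interval 11.5 to 11.9) and 3.84% (interval 3.67 to 4.01). Regions inside genes but away from their ends made up 46.4% of proliferative-restricted and 48.9% of quiescent-restricted regions. The authors' fold enrichment, which describes each peak within its own list, had a median of 2.52 in proliferative-restricted and 4.11 in proliferative shared regions, and of 2.58 in quiescent-restricted and 4.63 in quiescent shared regions. The gene table used gives no strand, so an end can be either the start or the end of transcription.

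Among strongly enriched regions, more were restricted to the quiescent list than to the proliferative list. The strongest quiescent-restricted regions lay inside RAB27A, RAD9B, FAM241A, MYO1D, PARD3B and EPHB4, near RXYLT1 and TMEM247, and at 2 further sites on chromosomes 1 and 16. The strongest proliferative-restricted regions lay inside MARCHF11, LIMS1, JAM2 and CUL2 and 20439 bp from CCDC200, and the other 5 had no protein-coding gene within 50 kb. Of regions with a −log10 q of at least 10 in their own list, 2926 of 75305 quiescent regions (3.89%, interval 3.75 to 4.03) and 1016 of 66600 proliferative regions (1.53%, interval 1.44 to 1.62) had no overlap in the other list. At a −log10 q of at least 20 these were 528 quiescent regions (1.13%) and 37 proliferative regions (0.101%). Between the 50000 strongest regions of each list and the 100000 strongest of the other, the numbers without overlap were 981 quiescent and 461 proliferative, a ratio of 2.13 against 2.88 and 14.3 at these thresholds, and 1312 and 823 (1.59) with regions under 200 bp left out. Over all regions there were 0.922 quiescent-restricted for each proliferative-restricted region; the number of shared regions was close in both lists, so this value follows the lengths of the lists.

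The strongest quiescent-restricted region was on chromosome 1 from 633957 to 634104, inside the span of LOC102724250, with a fold enrichment of 19.5 and a −log10 q of 221.8. The region in EPHB4, which encodes an ephrin receptor, was on chromosome 7 from 100803509 to 100803953, 1155 bp from an end of the gene, with a fold enrichment of 7.17. The strongest proliferative-restricted region, near CCDC200, was on chromosome 17 from 43251590 to 43251823, with a fold enrichment of 12.2 and a −log10 q of 65.6. The region in JAM2, which encodes a junctional adhesion molecule, was on chromosome 21 from 25699772 to 25700075, with a fold enrichment of 7.29. That in LIMS1, which encodes a focal adhesion protein, was on chromosome 2 from 108652386 to 108652895, with a fold enrichment of 7.42. Among regions with a −log10 q of at least 20, restricted ones were more often under 200 bp wide than shared ones. This held for 23.7% of quiescent-restricted against 0.536% of quiescent shared regions, and for 3 of 37 proliferative-restricted regions (8.11%) against 0.482% of proliferative shared regions. The region on chromosome 1 was 148 bp wide. Those on chromosome 16, near RXYLT1 and in RAB27A, RAD9B and PARD3B were also narrow, at 170, 162, 176, 179 and 197 bp. The other named quiescent-restricted regions were 344 bp or wider, and the named proliferative-restricted ones 212 bp or wider. Whether the narrow regions reflect stacks of reads at repeated sequence rather than open chromatin was not tested.

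**Figure D1:**
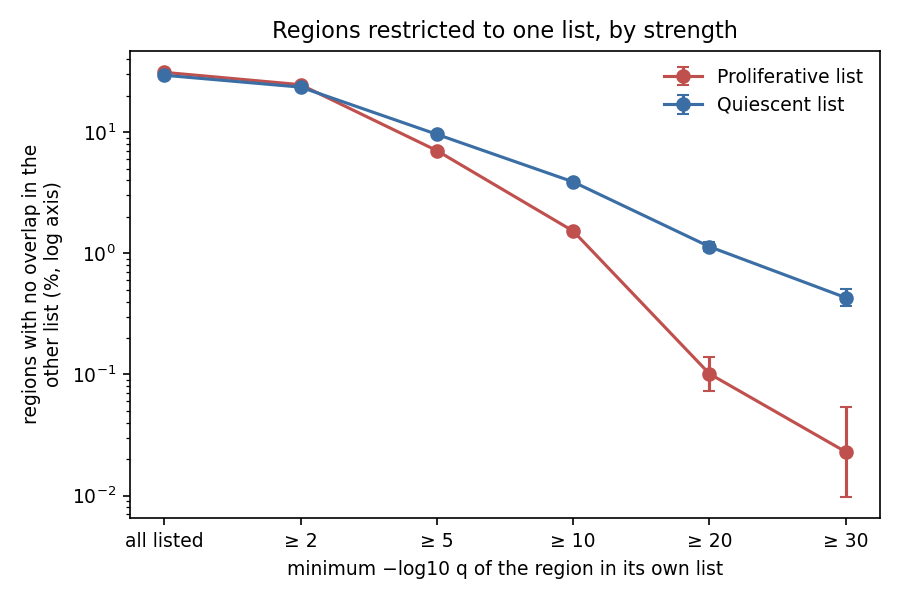
Percent of the regions of each list with no overlap in the other list (log axis) against the minimum −log10 q of the region in its own list, with 95% Wilson intervals. The lists lie close together over all regions, at 31.1% and 29.5%, and at a minimum of 20 the quiescent list is at 1.13% and the proliferative list at 0.101%.

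Extracellular matrix genes carried more quiescent-restricted regions, and sterol and lipid, vascular regulator and contractile genes more proliferative-restricted ones, but only the first balance stood apart from random gene lists. Among restricted regions with a −log10 q of at least 5, where 40.7% of all such regions were proliferative, contractile genes (44.4%) and vascular regulators (39.5%) also had more quiescent-restricted regions. The 22 matrix genes had 112 quiescent-restricted and 85 proliferative-restricted regions, a proliferative share of 43.2% (interval 36.4 to 50.1) at percentile 1.13 of 10000 matched random lists. Quiescent-restricted regions outnumbered the others at 13 of these genes. Among them, TNC, encoding tenascin C, had 8 quiescent-restricted regions against 1, most with a −log10 q under 5. COL1A2, encoding a chain of type I collagen, had 8 against 2. Proliferative-restricted regions outnumbered quiescent-restricted ones at 4, including COL5A2 with 13 against 7 and FN1, encoding fibronectin, with 10 against 7. This was the only one of 19 lists outside the central 95% of its random lists, and about 1 of 19 is what chance gives. It lay inside that range under 6 of 7 alternatives, for example when regions were assigned to genes within 10 kb, where its percentile was 9.51, and when only restricted regions with a −log10 q of at least 5 were counted, where it was 33.4.

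Contractile genes had 89 proliferative-restricted and 69 quiescent-restricted regions, a proliferative share of 56.3% at percentile 93.6. The percentile was 98.9 with assignment within 10 kb and 29.6 with assignment to the nearest gene end. At a −log10 q of at least 5 the counts were 16 against 20 (percentile 71.3), and at 10 they were 3 against 7 (percentile 68.0). CALD1, encoding the actin-binding protein caldesmon, had 22 against 13, most with a −log10 q under 5, and VCL, encoding vinculin, 9 against 2. MYLK, encoding myosin light chain kinase, had 6 against 9 and the integrin gene ITGA8 8 against 11. Of the 19 contractile genes, 15 had a region of both lists at an end and 3 had none. DES, encoding desmin, had one in the proliferative list only, with a −log10 q of 3.30. The sterol and lipid genes had 38 proliferative-restricted and 23 quiescent-restricted regions, a share of 62.3% at percentile 96.6, at percentile 97.7 with assignment within 10 kb and at 81.6 with a −log10 q of at least 2 in both lists. FADS2, encoding a fatty acid desaturase, had 5 against 0 and MYLIP, encoding a ligase that targets the LDL receptor, 5 against 1. The cholesterol transporter gene ABCG1 had 3 against 7. All 19 had a region of both lists at an end. Vascular regulators had 109 against 83 (56.8%, percentile 96.9), led by the transcription factor genes MEF2C with 10 against 2 and MEF2A with 8 against 1. YAP1 had 2 against 5 and RUNX1 7 against 10. At a −log10 q of at least 5 this list had 15 against 23 (percentile 52.7), and at 10 it had 0 against 2 (percentile 5.75). Both lists reached an end at 19 of these 25 genes, HEYL had a region in the proliferative list only (−log10 q 1.62), and 5 had none.

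**Figure D2:**
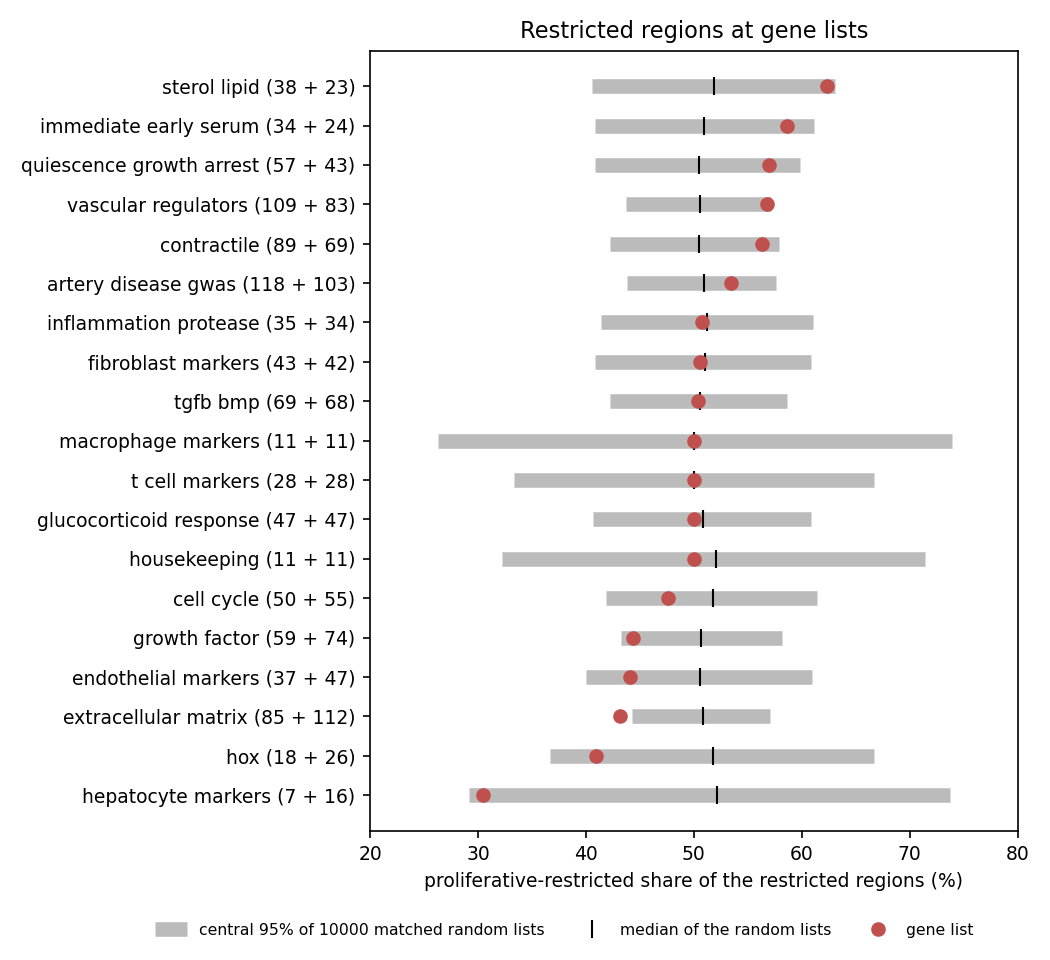
Share of proliferative-restricted among all restricted regions at each of 19 gene lists (points, percent), with the central 95% (bars) and median (ticks) of 10000 random lists matched on the number of regions per gene; the numbers in brackets are proliferative-restricted plus quiescent-restricted regions. Only the extracellular matrix point, at 43.2%, lies outside its bar, which runs from 44.3% to 57.0%.

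Cell cycle genes had a region of both lists at an end in 28 of 28 cases, in cells with serum and without. Their restricted regions numbered 50 proliferative and 55 quiescent (47.6%, percentile 20.8), and 3 and 12 at a −log10 q of at least 5 (percentile 5.47). MYBL2 had 5 proliferative-restricted and 0 quiescent-restricted regions and RRM2, encoding a ribonucleotide reductase subunit, 7 against 3. The kinase gene CDK6 had 6 against 14, the cyclin gene CCND2 0 against 5, and MKI67 1 against 5. At its upper-coordinate end MKI67 was listed on chromosome 10 from 128125373 to 128126969 in the proliferative list and from 128126230 to 128127001 in the quiescent list. Genes of quiescence and growth arrest had 57 against 43 restricted regions (57.0%, percentile 91.1), 26 against 26 with assignment within 10 kb (percentile 42.3) and 11 against 13 at a −log10 q of at least 5 (percentile 68.5). The transcription factor gene FOXO1 had 11 against 3 and the antiproliferative gene BTG1 4 against 0. CDKN1A, encoding the cell cycle inhibitor p21, had 2 against 6, and SESN3 had 2 against 5. CDKN1A was the 1 of 21 genes with a region at an end in the quiescent list only. These end regions of CDKN1A were weak, with a −log10 q of 2.64 and 1.90 and a fold enrichment of 1.86 and 1.99. A region of both lists lay at an end of 19 genes and of neither at 1.

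Serum response genes of the immediate early class had 34 proliferative-restricted and 24 quiescent-restricted regions (58.6%, percentile 93.4), 12 against 11 with assignment within 10 kb (percentile 53.1) and 7 against 8 at a −log10 q of at least 5 (percentile 74.8). JUN had 4 against 0, DUSP5, encoding a phosphatase of MAP kinases, 6 against 2, and FOS 3 against 1. Both lists had a region at an end of 20 of these 22 genes and neither list at 2. Growth factor genes had 59 against 74 (44.4%, percentile 5.01). The percentile was 1.42 with assignment within 10 kb, 22.3 with regions under 200 bp left out, and 48.6 and 75.8 for restricted regions with a −log10 q of at least 5 and 10. PDGFB, encoding a platelet-derived growth factor chain, had 0 against 6, FGF5 1 against 5 and PDGFC 6 against 3. Both lists had a region at an end of 17 of the 20 genes and neither list at 3. TGF-beta and BMP pathway genes had 69 against 68 (50.4%, percentile 49.1), or 46 against 62 with a −log10 q of at least 2 in both lists (percentile 6.98), with LTBP2 at 10 against 5 and BAMBI at 3 against 0, and 15 of 18 had a region of both lists at an end. Inflammation and protease genes had 35 against 34 (50.7%, percentile 46.0), but 14 against 23 with assignment within 10 kb (percentile 4.02) and 32 against 18 with regions under 200 bp left out (percentile 96.4). The cytokine gene IL6 had 4 against 1, the chemokine gene CXCL2 0 against 3 and NFKBIA 2 against 5, and 18 of 19 had a region of both lists at an end. Glucocorticoid response genes had 47 against 47 (50%, percentile 43.6), with CRISPLD2 at 9 against 3, KLF15 at 4 against 9 and FKBP5 at 2 against 6. An end was reached by both lists in 13 of these 14 genes. At NR3C1, encoding the glucocorticoid receptor, it was reached by the quiescent list only, with a −log10 q of 3.39. That call holds for the window of 1 kb only. With 2 kb, both lists reached an end of all 14 genes, NR3C1 included.

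At genes near coronary artery disease loci, 118 proliferative-restricted and 103 quiescent-restricted regions were found (53.4%, percentile 77.3). PHACTR1 had 19 against 10 and ZEB2 6 against 9, while PDGFD had 12 against 11 and TCF21 1 against 0. A region of both lists lay at an end of 20 of the 23 genes, BCAR1 had one in the proliferative list only (−log10 q 2.55), and 2 had none. HOX genes, which set position along the body axis, had 18 against 26 (40.9%, percentile 7.85). The percentile was 1.45 with regions under 200 bp left out, and 17.4 and 31.1 for restricted regions with a −log10 q of at least 5 and 10. Both lists had a region at an end of 16 of 29 HOX genes. At 3 HOX genes, including HOXA13, only the proliferative list did, and at 5, including HOXC10 and HOXB7, only the quiescent list. With a window of 2 kb, both lists had a region at an end of 22 of the 29 genes, so at least some of these calls depend on the window. HOXC10 and HOXD8 had 0 proliferative-restricted and 3 quiescent-restricted regions each. Housekeeping genes had 11 against 11 (50%, percentile 41.7), with YWHAZ at 6 against 3 and ACTB at 0 against 4, and 11 of 14 had a region of both lists at an end. Of the others, TUBB and RPS18 lie in long stretches that held no region of either list.

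**Figure D3:**
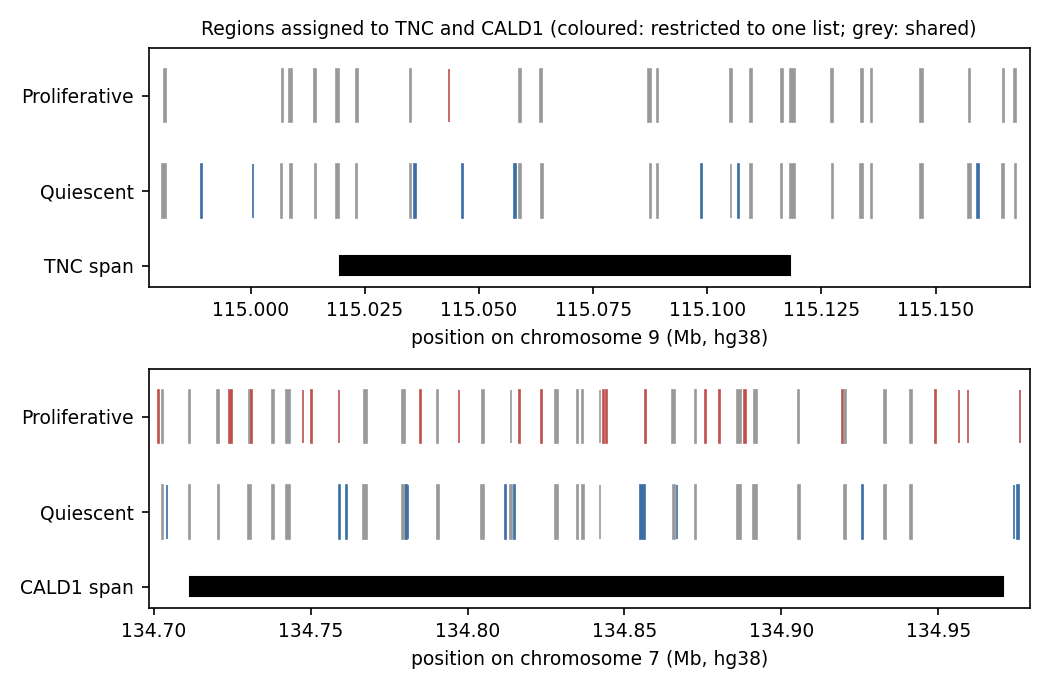
Regions of each list assigned to TNC on chromosome 9 and to CALD1 on chromosome 7, against position in Mb of hg38; coloured bars are restricted to their list, grey bars are shared, and the black bar is the gene span. TNC has 8 quiescent-restricted and 1 proliferative-restricted region, and CALD1 has 13 and 22.

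Over the genome, the genes with the largest excess of proliferative-restricted regions were GRID1, encoding a glutamate receptor subunit, with 26 against 7, the phosphodiesterase genes PDE4B with 26 against 8 and PDE4D with 49 against 31, GALNT13 with 18 against 3, FAT3 with 25 against 10, MCTP1 with 20 against 5, CRACDL with 18 against 4 and HS6ST3 with 21 against 7. The largest quiescent excess was at KCNMA1, encoding a calcium-activated potassium channel of smooth muscle, with 33 against 14. It was followed by FOXP1 with 31 against 16, CSMD2 with 28 against 13, APBB2 with 21 against 7, VPS13B with 23 against 9, PTPRG with 27 against 13, EXOC4 with 22 against 9 and NAALADL2 with 29 against 16. An excess of at least 10 in either direction was seen at 74 genes, against a median of 54 (range 34 to 77) when the list of origin was shuffled 1000 times over the restricted regions, and 6 of the shuffles gave as many. The largest single excess did not stand apart: the proliferative one of 19 was reached in 476 shuffles and the quiescent one of 19 in 212.

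Ends of endothelial and fibroblast markers often carried a region in both states. Both lists had a region at an end of 10 of 12 endothelial and 10 of 12 fibroblast markers, of 4 of 12 macrophage, 4 of 12 T cell and 2 of 12 hepatocyte markers; over all genes the share was 69.1%. With a window of 2 kb the counts were 12, 12, 6, 8 and 6 in the same order, and the share over all genes was 74.6%. Differences between these small groups were not tested. These counts take no account of strength. For named markers with an end in both lists, the −log10 q follows, proliferative list first. It was 13.4 and 11.5 at TEK, 2.85 and 1.98 at VWF, and 3.38 and 7.27 at ERG. At the fibroblast markers SCARA5, MFAP5 and COL14A1 (lower-coordinate end) it was 36.5 and 41.6, 53.6 and 62.1, and 30.8 and 54.0. Restricted regions at endothelial markers numbered 37 proliferative and 47 quiescent (44.0%, percentile 11.4), or 36 and 30 with regions under 200 bp left out (percentile 60.9), with TEK at 4 against 0, VWF at 8 against 5, ERG at 5 against 10 and PECAM1 at 3 against 7. Fibroblast markers had 43 against 42 (50.6%, percentile 46.9), with SCARA5 at 8 against 4, COL14A1 at 3 against 9 and MFAP5 at 0 against 3. Macrophage markers had 11 against 11 (50%, percentile 46.6) and T cell markers 28 against 28 (50%, percentile 49.0), the latter with CD247 at 8 against 2 and CD2 at 0 against 4. Hepatocyte markers, taken as a control, had 7 against 16 (30.4%, percentile 3.33), or 8 against 11 with a −log10 q of at least 2 in both lists (percentile 20.3), with HNF4A at 1 against 7 and CYP3A4 at 0 against 3. An end was listed in 1 state only at PECAM1, CD6 and CYP2E1 (proliferative) and at TYROBP, ITGAM, OGN and APOC3 (quiescent). In this order, the −log10 q of these end regions was 3.65, 7.74, 5.55, 2.44, 2.39, 13.4 and 1.965. These calls are for the window of 1 kb. With 2 kb, PECAM1 and OGN had a region of both lists at an end, as did all 12 markers of their groups.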

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

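All tests in this part were chosen after the results were seen. Peaks outside chromosomes 1 to 22 and X stood out as signal in data the comparisons did not use: there were 546 in the proliferative and 508 in the quiescent list.

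Strong regions restricted to the quiescent list outnumbered strong proliferative-restricted ones, with 2926 against 1016 at a −log10 q of at least 10. A higher enrichment over the whole quiescent list could produce this, since the same region then passes a fixed threshold more easily. With equal list lengths, the 50000 strongest regions of each list against the 100000 strongest of the other, 981 quiescent and 461 proliferative regions had no overlap, a ratio of 2.13 (counting interval 1.91 to 2.38), which argues against that as the whole cause; simulated lists with uniformly lower enrichment gave 0.983 to 1.07. With regions under 200 bp left out, the ratio was 1.59 (interval 1.46 to 1.74), which spans the bound of 1.5 set for the test, so for wider regions a list-wide difference stays open. The shortest width each list allows is argued against by the 4.44% of these quiescent-restricted regions that were narrower than any proliferative region, and a change of chromatin on serum withdrawal or unequal shares of the donors in the pooled lists were not tested.

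Strong restricted regions were more often narrow than shared regions above the same minimum strength. Of quiescent-restricted regions with a −log10 q of at least 20, 23.7% were under 200 bp, against 0.536% of shared ones. Only this minimum was matched: 136 of the 528 restricted regions reached 30, against 31584 of all 46577 quiescent regions. Shared quiescent regions at the lower minimum of 5 were under 200 bp in 3.63%, which argues against width following strength alone. A narrow region has fewer positions for an overlap of 1 bp, so the definition of restricted may add to the difference. That part was not tested. In the proliferative list 3 of 37 restricted regions with a −log10 q of at least 20 were under 200 bp. In both lists most strong restricted regions were thus at least 200 bp wide, and of quiescent-restricted regions of every strength 43.0% were under 200 bp. Stacks of reads at repeated sequence, as possibly at the region in LOC102724250 on chromosome 1, stay open because no repeat annotation was used here.

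Gene-rich stretches held no region of either list. There were 30 stretches of at least 500 kb with at least 5 protein-coding genes, 40.7 Mb with 625 genes, among them chromosome 6 from 28490445 to 31374135 with TUBB and IER3, chromosome 6 from 32610108 to 33490405 with RPS18, chromosome 15 from 29924983 to 32951896 with GREM1, and the stretch of chromosome 16 with MYH11. Closed chromatin is argued against for the stretches of chromosome 6 by the 2 housekeeping genes inside them, TUBB and RPS18. Reads that align equally well to alternate copies of a locus and are then discarded may explain part of it: 76 peaks of both lists lay on contigs named as alternate loci, so such contigs were among those the reads could align to. Whether each stretch has such a copy was not tested, and the lengths and gene minimum were chosen after the stretch with MYH11 had been seen.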

How the results depend on the processing

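The alternatives called added here were chosen after seeing the data. No paired analysis was possible because each list pools the 5 donors of its state, and leaving out each donor was not possible for the same reason. The motif shares and their alternatives were not run. Depth limits which weak regions are listed at all. The cause of the changes below was not tested, except that a stricter overlap or window admits fewer regions by construction.

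The shared share of proliferative and quiescent regions was 74.0% and 75% with a −log10 q of at least 2 in both lists, 83.7% and 83.6% between the 50000 strongest regions, 57.3% and 58.8% with a reciprocal overlap of 50%, 54.7% and 56.2% with summits within 100 bp, and 93.0% and 90.4% for regions with a −log10 q of at least 5 against every region of the other list. Added alternatives gave 72.2% and 75.7% with regions of at least 200 bp, and 71.9% and 73.7% within 500 bp. At a −log10 q of at least 5 the proliferative share was the higher one; between the 50000 strongest, equal list lengths hold the shares close together, and their intervals overlapped.

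The share of restricted regions at gene ends was 4.12% (proliferative) and 8.27% (quiescent) among the 50000 strongest, 4.40% and 4.68% with reciprocal overlap, 6.39% and 6.74% by summits, 1.56% and 2.05% with a window of 500 bp, 6.34% and 6.82% with 2 kb, 2.96% and 4.19% at a −log10 q of at least 5 and, added, 7.99% and 8.53% with genes of every biotype. At a −log10 q of at least 2 the quiescent share was 4.17%, and the proliferative share stayed within its interval. The quiescent share was the higher one under each of these 8 alternatives.

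The number of quiescent-restricted for each proliferative-restricted region, 0.922, and all its alternatives were added. It was 1.01 between the 50000 strongest, where equal lengths hold it near 1, 1.46, 2.88 and 14.3 at a −log10 q of at least 5, 10 and 20, and 2.13 for the 50000 against the 100000 strongest. It stayed below 1 under the other 5 alternatives.

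For gene lists the percentile was compared and not the share, a choice made after the shares were seen to move with the strength of the regions. Of 130 recomputed percentiles, 117 stayed on their side of the bounds of the central 95%, and none that lay outside, before or after, crossed 50. The extracellular matrix list moved inside at 9.51 (assignment within 10 kb), 2.86 (−log10 q of at least 2) and, added, 5.43 (at least 200 bp), 6.09 (nearest gene end), 33.4 and 32.2 (restricted regions with a −log10 q of at least 5 and 10), and kept its side only with assignment within 100 kb, at 0.57. Moving outside were, within 10 kb, contractile at 98.9, growth factor at 1.42 and sterol and lipid at 97.7; HOX at 2.22 (−log10 q of at least 2) and 1.45 (at least 200 bp); vascular regulators at 98.6 (at least 200 bp); and sterol and lipid at 98.98 (restricted with a −log10 q of at least 5, 8 regions). Among stronger restricted regions (−log10 q of at least 5 and 10), vascular regulators were at 52.7 and 5.75, growth factor at 48.6 and 75.8, HOX at 17.4 and 31.1 and contractile at 71.3 and 68.0. Inside the central 95%, the percentile over the alternatives ran from 4.02 to 96.4 for inflammation and protease, 5.47 to 85.9 for cell cycle, 6.98 to 90.9 for TGF-beta and BMP, 7.75 to 87.8 for housekeeping, 2.75 to 36.0 for hepatocyte, 11.4 to 45.6 for macrophage, 12.2 to 80.7 for endothelial, 18.3 to 69.4 for fibroblast, 25.3 to 66.6 for T cell, 20.7 to 64.6 for glucocorticoid response, 42.3 to 87.7 for growth arrest, 53.1 to 94.4 for immediate early and 55.6 to 94.8 for artery disease genes. For 3 lists no restricted region had a −log10 q of at least 10. Of 38 recounts of genes with a region of both lists at an end, 36 stayed within 1.5 times; T cell markers rose to 8 and hepatocyte markers to 6 with 2 kb.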

Other observations

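The percentiles 96.6, 93.6 and 29.6 below repeat values of the gene list balance, of which the first and second were planned. The other tests in this part, and the use of these values as tests, were chosen after the results were seen. Several large genes held strong restricted regions of 1 list only. At a −log10 q of at least 10, ANK3, CCNY, FOXP1, MIPOL1, PLCB1, PTPRG, TTC28 and VPS13B each held 4 quiescent-restricted and 0 proliferative-restricted regions. VEGFA, encoding a vascular growth factor, the homeobox gene MEIS2, the integrin gene ITGB5 and SLIT3 were among 19 genes with 2 proliferative-restricted and 0 quiescent-restricted regions. Neither count stood apart from chance, since shuffles of the list of origin gave 1 to 12 and 7 to 34 genes.

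On chromosome X, 560 proliferative and 862 quiescent regions were restricted, a proliferative share of 39.4% (interval 36.9 to 42.0), against 52.2% on the autosomes (interval 51.9 to 52.5). Chromosomes 17 and 22 had shares of 48.5% and 48.2%. Of all listed regions, 2912 proliferative and 3201 quiescent ones lay on chromosome X, against 167662 and 162943 on the autosomes. The lists thus differed on chromosome X as a whole, and unequal shares of the donors in the pooled lists were not tested as a cause.

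Neighbouring restricted regions under 1 kb apart came from the same list in 41.9% of 7194 pairs, below the 48.0 to 52.0% of 1000 shuffles, and in 47.0% at 1 to 5 kb, also below the shuffles. The distance at which the caller joins peaks of the same list was not used here, and its part in these values was not tested. At 5 to 50 kb, a range picked after narrower ones had been seen, the share was 50.74% of 65227 pairs, and the highest of the shuffles was 50.71%. Within it, 1 shuffle was as high at 5 to 10 kb, 94 at 10 to 20 kb and 44 at 20 to 50 kb; with shuffles inside each chromosome these were 7, 118 and 70, and 0 over the whole range.

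A hypothesis was that genes induced when cells lack lipoproteins would carry more quiescent-restricted regions. The sterol and lipid list, at percentile 96.6, also holds ABCA1, ABCG1, NR1H3 and MYLIP, which belong to the opposite response to sterol excess, so it was tested without them. The other 15 genes had 23 proliferative-restricted and 9 quiescent-restricted regions, a proliferative share of 71.9% (interval 54.6 to 84.4) at percentile 99.6 of matched random lists. The interval lies above the random median of 52.2%, which argues against the hypothesis at these 15 genes in these 2 lists, within counting error. For the whole sterol and lipid list the interval, 49.75 to 73.39, spans its random median of 51.9%. The argument thus rests on a choice of genes made after the values had been seen. The same hypothesis for contractile genes, which mature smooth muscle uses, gave a share of 56.3% (interval 48.5 to 63.8). That interval lies above the 42.2% below which 2.5% of random lists fall, which argues against an excess beyond the range of random lists. It spans the random median of 50.5%, at percentile 93.6, so a smaller excess stays open. Assignment to the nearest gene end gave 50 against 54 contractile regions, a share of 48.1% at percentile 29.6. No interval was set against the bound there, so the argument holds for assignment to gene spans only. The bounds of these tests were changed after the values had been seen; the first, a percentile of 50 or above, counted against both hypotheses, and the second, on the whole sterol and lipid list, against neither.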
